A study of Arabidopsis thaliana with 16 samples.

How the data were processed

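The data are 16 RNA sequencing libraries of Arabidopsis thaliana made with a stranded mRNA kit, with 2 biological replicates in each of 8 groups. The groups are seedlings of Col-0 and 35S:CO at ZT16 and petals of Col-0, 35S:CO and co-10 at ZT4 and at ZT16. The values are FPKM as deposited by the authors, with 1 column per library and 32833 loci, and all 16 columns were used. The unit was read from the values, which are not whole and whose sums differ between libraries, from 582971 to 586630 in seedlings and from 615630 to 1096390 in petals. The submitters' notes name HISAT2, FastQC and the TAIR10 build; the quantifier, its version and the annotation release are not given in the sources used here. Positions come from TAIR10.1, in which 32548 loci were matched by locus identifier, and the other 285 are chloroplast and mitochondrial loci.

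FPKM carry no counts, so depth was estimated. Among the 21307 loci with 1 annotated transcript, low values times transcript length should be multiples of the value of a single read, and the step that gave the most whole multiples was taken. Of the low values, up to 20 reads, 45.5% to 50.1% in seedlings and 27.2% to 41.7% in petals lay within 0.02 of a whole number, against 4% for values spread evenly. The steps correspond to 55970000 to 63340000 reads in seedling libraries and 5220000 to 22010000 in petal libraries. In seedlings 25.9% to 27.4% of the whole low values stood at 1 read, but in petals 5.2% to 24.7%, with the most frequent number at 7 reads in co-10 ZT4 replicate 2 and 3 in 35S:CO ZT16 replicate 1, which was not explained and leaves petal depths uncertain. These depths are estimates and give no counting interval for single values.

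Values were taken as log2(FPKM + 1). Genes at 1 FPKM or more in at least 2 libraries of a fit were tested by limma 3.58.1 with a trended, robust prior variance (statmod 1.5.0, R 4.3.3). The petal fit held 12 libraries and 6 group means, the seedling fit 4 libraries and 2 group means, and the interaction with tissue was tested over all 16 libraries and 8 group means. The 13 comparisons were 35S:CO with Col-0 in seedlings, in petals at ZT4 and at ZT16, co-10 with Col-0 and 35S:CO with co-10 at each time, ZT16 with ZT4 in each genotype, and the interactions of 35S:CO with time, of co-10 with time and of 35S:CO with tissue. All tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. Differences are given ± SE from the fit and FPKM as mean ± SD with n = 2. In each called genotype, time or interaction difference that is named, the direction was read from both libraries of each group. A gene at 0 in a whole group is described as listed at 0, and its fitted difference depends on the added 1 FPKM.

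Genes were named by a rule: CO, then up to 8 genes with the largest difference each way (4 for time of day) among called genes with a mean log2 value of at least 1 and no overlap between the groups, and for each list every called member, at least 4 in all where a member was called, or 2 where none was. The groups, the comparisons, the lists, this rule and most other settings were chosen before the data were examined. Shared calls between comparisons were tested across genes by two-sided Fisher's exact test in R.

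The 22 gene lists, with 365 members, were transgene, flowering, floral organ identity, clock morning-phased, clock evening-phased, jasmonate biosynthesis, jasmonate catabolism, jasmonate signalling, jasmonate-responsive defence, senescence, chlorophyll breakdown, autophagy, nutrient remobilisation, ethylene, abscission, abscisic acid and drought, salicylic acid defence, flavonoid and anthocyanin, photosynthesis and markers of pollen and anther, of carpel, ovule and seed, and of root. The transgene list holds CO alone. In 1 case a member was left out because its locus carries another symbol in the reference table. Lists with at least 3 tested members were tested, 19 in seedlings, 20 in petals and 21 over all libraries; the root markers had 1 tested member in petals, IRT1, which was not called in any petal comparison. Camera compared each list with all other genes at a preset correlation of 0.01 and again with an estimated correlation, and p was adjusted over the lists of a comparison. Camera with the preset correlation called 86 lists in the 13 comparisons, and with the estimated correlation it called 0 of them. The fry p tests whether the genes of a list move on balance in 1 direction, and its mixed p whether they change in either direction; neither compares a list with other genes. Fry approximates a rotation test on the residuals of the whole fit and is not exact, so with 2 libraries per group its p is to be read as approximate. Counts adjusted over the list alone use the same gene p-values, adjusted among the tested members of the list.

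The pipeline was tested on simulated data with the spread of these libraries, 5 sets of 200 changed genes. The changed genes were drawn from those with a mean log2 value of at least 3, so the shares below do not cover lower genes. Variances were drawn from the fitted prior, and genes were simulated independently. In petals 0.606% of genes changed by 1 on the log2 scale were called, 51.0% of those changed by 2 and 87.8% of those changed by 3; in seedlings the shares were 77.6%, 98.2% and 99.1%. False calls made up 8.43% of calls in petals and 6.81% in seedlings, and camera called 5 of 5 changed lists and 0 of 5 unchanged ones. The correlation of 2 comparisons with a shared control was set against 20 simulations without any difference. Sharing of sequence within gene families was measured as the percent of 75-base stretches found in another family member (pysam 0.24.0). Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. The alternatives tried were quantile normalization, no filter, a pseudocount of 0.1, a replicate block, only the 4 libraries compared, all 16 libraries in one fit, a 2-fold limit, leaving out each library of the compared groups in turn and, chosen after seeing the data, rescaling, array weights, a mean of at least 5 FPKM and other library orders.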

Results

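Transcript levels were measured by strand-specific mRNA sequencing in 16 libraries of Arabidopsis thaliana, which fall into 8 groups of 2 biological replicates each. Whole seedlings at an age of 10 days were collected at ZT16 from wild type Col-0 and from 35S:CO, a line that overexpresses the flowering-time regulator CONSTANS (CO). Petals were collected at ZT4 and at ZT16 from Col-0, from 35S:CO and from co-10, a null mutant of CO. ZT counts hours from lights on, so ZT16 is the hour at which the lights go off. The authors' values are FPKM for 32833 loci, and the depth, read from the smallest step between low values, was 55970000 to 63340000 reads per seedling library and 5220000 to 22010000 per petal library. Among petals, co-10 ZT4 replicate 2 had the lowest estimate and Col-0 ZT4 replicate 2 one of 7670000. The number of loci listed at 0 ran from 7975 to 8361 in seedlings and from 11490 to 18240 in petals. The 4 ribosomal RNA loci held 3.82% to 48.8% of the summed FPKM of petal libraries and 0.11% to 0.61% of that of seedling libraries. Across genes, which are not independent replicates, the replicates of a group correlated at r = 0.981 and 0.989 in seedlings and at 0.881 (co-10 ZT4) to 0.968 (35S:CO ZT16) in petals. The main axis of variation among petal libraries, with 46.5% of the variance, placed the 6 ZT4 libraries on one side and the 6 ZT16 libraries on the other. The next axis, with 13.5%, set co-10 ZT4 replicate 2 apart at a score of -104, against -24.8 to 34.6 for the other petal libraries.

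CO (AT5G15840, chromosome 5, 5170162 to 5173085, minus strand in TAIR10.1) was the manipulated gene, and its level checks the genotype labels. In seedlings it stood at 2.00 ± 0.136 FPKM (mean ± SD, n = 2) in Col-0 and 306 ± 12.6 FPKM in 35S:CO. In Col-0 petals it stood at 0.405 ± 0.421 FPKM at ZT4 and 0.114 ± 0.109 FPKM at ZT16, in 35S:CO petals at 443 ± 41.3 and 566 ± 83.9 FPKM, and in co-10 petals at 0.143 ± 0.166 and 0.113 ± 0.0714 FPKM. CO rose in 35S:CO by 6.68 ± 0.08 on the log2 scale in seedlings (± SE, adjusted p = 1.05e-04), by 8.33 ± 0.33 in petals at ZT4 (4.46e-07) and by 8.99 ± 0.33 at ZT16 (3.93e-07), in each case in 2 of 2 libraries. A difference between Col-0 and co-10 petals was not detectable at these levels. FT (AT1G65480, chromosome 1, 24331373 to 24333999, plus strand), which encodes the florigen and is the best known target of CO, went from 2.73 ± 0.779 to 161 ± 5.18 FPKM in seedlings, from 1.28 ± 1.81 to 148 ± 52.9 FPKM in petals at ZT4 and from 1.52 ± 0.230 to 583 ± 326 FPKM in petals at ZT16. In co-10 petals FT stood at 2.44 ± 2.89 and 1.14 ± 0.488 FPKM.

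**Figure D1:**
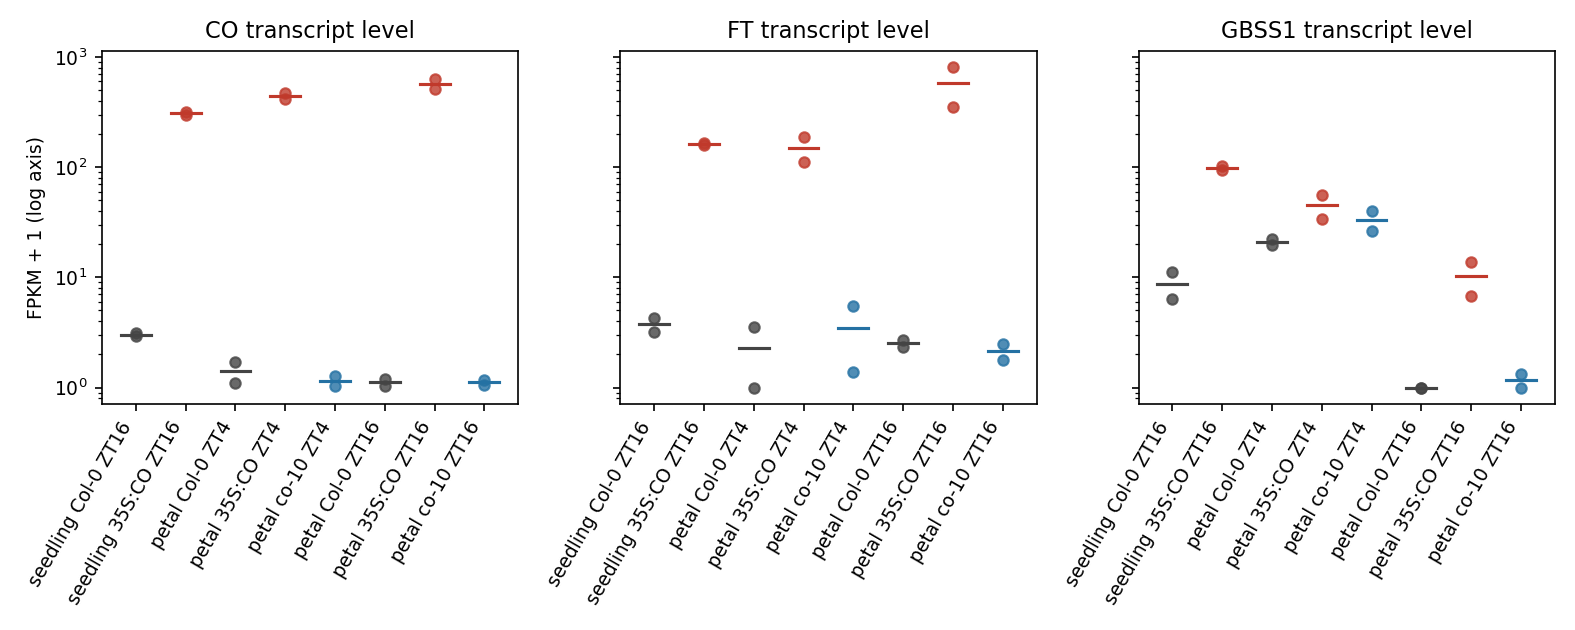
FPKM plus 1 on a log axis for CO, FT and GBSS1 in each library (points) with the mean of each group of 2 libraries (bars), by tissue, genotype and time. CO and FT lie above 100 FPKM in every 35S:CO library, and GBSS1 is listed at 0 in both Col-0 petal libraries of ZT16.

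In seedlings the comparison asks what CO overexpression changes at the end of the light period. Among flowering genes, FT rose by 5.46 ± 0.16 on the log2 scale (adjusted p = 5.89e-04), SOC1, a MADS-box activator of flowering, by 2.45 ± 0.09 (7.12e-04) and TSF, the closest relative of FT, by 2.15 ± 0.19 (0.0059). Large increases also held LEA3, a late embryogenesis abundant protein, at 6.47 ± 0.24, the light-harvesting gene LHCB2.3 at 5.35 ± 0.10, the cytidine deaminase CDA1 at 4.60 ± 0.10, the thionin THI2.2 at 4.36 ± 0.17 and the B-box gene BBX32 at 4.33 ± 0.13. SAG29, a sucrose transporter gene of senescing tissue, rose by 4.61 ± 0.27 (0.00316). ATMDAR2, a monodehydroascorbate reductase that regenerates ascorbate, fell by 4.37 ± 0.21 (0.00146), from 80.2 ± 8.78 to 3.00 ± 1.097 FPKM. Also lower were the spindle assembly factor TPX2 at -2.42 ± 0.14, the ubiquitin ligase LUL1 at -2.25 ± 0.14 and CIP1, which interacts with the light-signalling repressor COP1, at -2.17 ± 0.14. Of 19214 genes tested, 2252 changed and 1057 of them were higher and 1195 lower. Which direction held more genes depends on the setting, with 1130 higher and 869 lower after quantile normalization, 857 and 722 without a filter, 722 and 456 with a replicate block and 534 and 205 at the 2-fold limit. Leaving out 35S:CO replicate 1 lowered the count to 54 and leaving out 35S:CO replicate 2 to 138. Of the 113 genes named in the text or by the rule for named genes that passed, 33 passed without each library in turn, among them LEA3, FT, LHCB2.3, CDA1, THI2.2, BBX32, ATMDAR2, TPX2, CIP1, SOC1 and TSF.

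Among the fixed gene lists, the morning-phased clock genes stood out in seedlings: 9 of the 10 tested rose, over all genes and when adjusted over the list alone, with a median of 2.23 (camera adjusted p = 1.40e-12, and adjusted p = 0.304 with an estimated correlation). PRR7 rose by 2.76 ± 0.09, LHY by 2.65 ± 0.12, PRR9 by 2.52 ± 0.11 and CCA1 by 2.12 ± 0.14. Of the 11 evening-phased genes 2 rose, GI by 3.12 ± 0.10 and PRR5 by 2.69 ± 0.09, and ELF4 fell by 1.85 ± 0.13, while 8 did not pass; adjusted over the list alone, 4 rose and 3 fell. In the flowering list 7 of 21 rose, 2 fell and 12 did not pass (9 and 3 adjusted over the list alone; camera adjusted p = 2.49e-04, and adjusted p = 0.416 with an estimated correlation). The 2 that fell, SNZ and TOE1, are repressors of flowering, and GBSS1, a starch synthase gene in the same list, rose by 3.55 ± 0.27. Floral organ identity genes were higher in 4 of 5, also when adjusted over the list alone (camera adjusted p = 1.77e-05, and adjusted p = 0.416 with an estimated correlation), with SEP1 up by 2.43 ± 0.15. AP3 and PI of this list passed without each library in turn. The labels give an age but no developmental stage of the seedlings, so a difference in stage or organs between the genotypes was not separated. The photosynthesis list had 18 of 40 higher, 2 lower and 20 that did not pass, with 21 and 3 adjusted over the list alone (camera adjusted p = 5.32e-10, and adjusted p = 0.416 with an estimated correlation). LHCB2.1 rose by 3.82 ± 0.16 and LHCB3 by 2.30 ± 0.12, whereas RBCS1B, a Rubisco small subunit gene, fell by 1.85 ± 0.09.

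Camera called the 4 jasmonate lists upward in seedlings, while by fry none of them moved on balance (adjusted p = 0.059 to 0.162). In the biosynthesis list 2 of 16 rose and 14 did not pass, with 6 higher when adjusted over the list alone (camera adjusted p = 2.17e-05, and adjusted p = 0.424 with an estimated correlation). The 2 were JMT, which methylates jasmonic acid, by 4.00 ± 0.27 and OPR3, a reductase of the pathway, by 0.64 ± 0.09. In the catabolism list 4 of 7 rose and 3 did not pass, with 5 adjusted over the list alone (camera adjusted p = 2.13e-06, and adjusted p = 0.416 with an estimated correlation). JOX4, which hydroxylates jasmonic acid, rose by 2.93 ± 0.18 and CYP94B3, which oxidises its isoleucine conjugate, by 1.15 ± 0.12. In the signalling list 7 of 20 rose, 1 fell and 12 did not pass, with 7 and 2 adjusted over the list alone (camera adjusted p = 0.00338, and adjusted p = 0.425 with an estimated correlation). The repressor genes JAZ9 and JAZ10 rose by 2.84 ± 0.18 and 1.99 ± 0.24, and JAZ4 fell by 0.80 ± 0.11. Of the jasmonate-responsive defence genes 4 of 13 rose and 9 did not pass, with 8 adjusted over the list alone and a median of 1.47 (camera adjusted p = 7.55e-07, and adjusted p = 0.416 with an estimated correlation). They were NAC019, NAC055, HEL and THI2.1, from 2.29 ± 0.29 down to 1.34 ± 0.27.

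Senescence genes were higher in 6 of 29 in seedlings, lower in 1 and did not pass in 22, with 7 and 2 adjusted over the list alone (camera adjusted p = 1.47e-05, and adjusted p = 0.416 with an estimated correlation). SAG13, a dehydrogenase-like senescence marker, rose by 3.87 ± 0.27 and the ribonuclease gene RNS1 by 1.90 ± 0.26. In the nutrient remobilisation list 5 of 19 rose, 3 fell and 11 did not pass, with 12 and 4 adjusted over the list alone (camera adjusted p = 4.45e-04, and adjusted p = 0.416 with an estimated correlation). GLN1;4, a cytosolic glutamine synthetase, rose by 2.14 ± 0.17 and PPDK, a pyruvate phosphate dikinase, by 1.94 ± 0.08, while the sucrose exporter gene SWEET12 was lower at -1.70 ± 0.08. In the salicylic acid defence list 2 of 13 rose and 11 did not pass, with 3 adjusted over the list alone (camera adjusted p = 2.49e-04, and adjusted p = 0.416 with an estimated correlation), PR5 by 1.94 ± 0.19 and SARD1 by 0.83 ± 0.17. The other lists were not called: abscisic acid and drought had 3 higher, 1 lower and 16 not passing (3 and 5 adjusted over the list alone), chlorophyll breakdown 2, 1 and 4 (2 and 1), ethylene 0, 2 and 13 (1 and 2), flavonoid and anthocyanin 1, 2 and 13 (1 and 2) and abscission 0, 3 and 6 (0 and 4). Autophagy, with 14 tested, and the root markers, with 8, held no gene that passed by limma, over all genes or adjusted over the list alone; autophagy had a median of -0.02 and a mean of 0.03, with the test upward. Of the pollen and anther markers TUA1, an alpha-tubulin of pollen, rose, and too few members of that list and of the carpel, ovule and seed markers were tested for a list result in seedlings. By fry 6 of the 19 lists moved on balance in 1 direction: the clock lists, flowering, floral organ identity, photosynthesis and abscission.

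In petals at ZT4, 4 h after lights on, the comparison of 35S:CO with Col-0 found few genes. Besides CO, FT rose by 6.26 ± 0.71 (adjusted p = 0.00511), LEA3 by 4.60 ± 0.47 (0.00214) and the ammonium transporter gene AMT1;2 by 4.32 ± 0.36 (5.86e-04). PDX1.1 and PDX1L4, of a family of vitamin B6 synthesis genes, rose by 3.01 ± 0.38 and 2.86 ± 0.41, but 32.7% and 43.9% of their 75-base stretches are shared within the family, so reads of the pair are partly interchangeable. HIPP22, a heavy-metal-associated protein gene, rose by 2.98 ± 0.38, MIPS2, a myo-inositol phosphate synthase, by 2.93 ± 0.35 and MS2, a fatty acyl reductase of pollen wall formation, by 2.66 ± 0.38. LUL1 fell by 4.52 ± 0.36 (4.04e-04), and ATMDAR2, at 194 ± 21.3 FPKM in Col-0, was listed at 0 in both 35S:CO libraries (3.81e-07). AT3G02555 fell by 3.64 ± 0.44. Of 17876 genes tested, 19 changed, 16 higher and 3 lower; 1109 had an unadjusted p under 0.05. The count was 9 without Col-0 ZT4 replicate 1 and 7 without 35S:CO ZT4 replicate 1, and without 35S:CO ZT4 replicate 2 there were 9 higher and 14 lower. Of the 11 named genes that passed LEA3, AMT1;2, ATMDAR2 and LUL1 passed without each library in turn.

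Besides CO, FT was the only list member called at ZT4, out of 17 flowering genes tested. Camera called 3 lists upward, with no member past the threshold in any of them. Salicylic acid defence had a median of 0.84 over 12 members, with 3 higher when adjusted over the list alone (camera adjusted p = 8.58e-05, and adjusted p = 0.501 with an estimated correlation). Senescence had a median of 0.27 over 30, with 1 adjusted over the list alone (0.0128, and adjusted p = 0.887 with an estimated correlation). Ethylene had a median of 0.20 over 14, with 0 adjusted over the list alone (0.038, and adjusted p = 0.887 with an estimated correlation). No list moved on balance by fry. Adjusted over the list alone, 2 nutrient remobilisation genes were higher and 1 lower, 2 abscisic acid and drought genes and 1 jasmonate biosynthesis gene were lower, 1 photosynthesis gene was higher, and of the flowering genes FT was higher and 1 lower. The median, mean and test of the abscission, flowering and pollen and anther lists differed in sign.

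In petals at ZT16 the same comparison gave more genes. FT rose by 7.74 ± 0.71 (adjusted p = 3.72e-04), TSF by 3.78 ± 0.58 (0.0104), LHY by 2.76 ± 0.48 (0.0215) and its relative RVE8 by 2.72 ± 0.35 (0.00351). LEA3 rose by 6.91 ± 0.47, LHCB2.3 by 5.87 ± 0.51, AMT1;2 by 5.09 ± 0.36, the arginase gene ARGAH2 by 5.06 ± 0.60, LEA4-5 by 4.87 ± 0.78 and PDX1.1 by 4.69 ± 0.38. CBL6, a calcineurin B-like calcium sensor (3.34e-06), GBSS1 (0.0041) and UP6 were listed at 0 in both Col-0 libraries and stood at 41.2 ± 0.173, 9.31 ± 5.00 and 22.9 ± 3.45 FPKM in 35S:CO. Rubisco activase, RCA, rose by 2.69 ± 0.36 (0.00456) and the Rubisco small subunit gene RBCS3B by 3.11 ± 0.56 (0.0243), with 15.0% of its stretches shared in its family. Lower were LUL1 at -3.61 ± 0.36 (5.92e-04), CCL at -3.61 ± 0.45, the cellulose synthase-like gene CSLE1 at -3.11 ± 0.41 and the calmodulin-like gene CML38 at -2.98 ± 0.48, and ATMDAR2, at 83.1 ± 20.3 FPKM in Col-0, was listed at 0 in both 35S:CO libraries (1.28e-06). DIN2, a dark-induced beta-glucosidase of the senescence list, fell by 2.84 ± 0.59 (0.0487). Of 17876 genes tested, 204 changed, 153 higher and 51 lower. The count was 63 without Col-0 ZT16 replicate 1, 82 without Col-0 ZT16 replicate 2, 48 without 35S:CO ZT16 replicate 1 and 57 without 35S:CO ZT16 replicate 2. Of the 29 named genes that passed, 11 passed without each library in turn, among them FT, LEA3, LHCB2.3, CBL6, AMT1;2, ARGAH2, PDX1.1, ATMDAR2, LUL1 and CCL.

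The lists of petals at ZT16 went both ways. Morning-phased clock genes had 2 of 10 higher and 8 that did not pass, with 4 adjusted over the list alone and a median of 0.81 (camera adjusted p = 4.51e-07, and adjusted p = 0.35 with an estimated correlation). Flowering had 3 of 17 higher, also when adjusted over the list alone (0.00461, and adjusted p = 0.35 with an estimated correlation). Photosynthesis had 2 of 40 higher, with 6 adjusted over the list alone (0.00461, and adjusted p = 0.749 with an estimated correlation); RBCS2B, at 2.84 ± 0.60, did not pass (0.0508). Abscisic acid and drought had COR15A and COR15B, cold-induced chloroplast proteins, higher by 2.66 ± 0.41 and 3.46 ± 0.61, and ABF3, a transcription factor of abscisic acid responses, lower by -2.15 ± 0.35, with 16 not passing and 3 and 1 adjusted over the list alone (0.0374, and adjusted p = 0.437 with an estimated correlation). Jasmonate biosynthesis was lower as a group, with 15 of 16 members below 0, a median of -0.41, none past the threshold by limma and 2 lower when adjusted over the list alone (0.00129, and adjusted p = 0.437 with an estimated correlation). Jasmonate-responsive defence, with a median of -0.72 over 12 members, had none past the threshold by limma, over all genes or adjusted over the list alone (0.0141, and adjusted p = 0.437 with an estimated correlation); VSP2, a vegetative storage protein gene, stood at -0.71 ± 0.58. Senescence had 1 of 30 lower and 29 that did not pass, with 1 higher and 3 lower adjusted over the list alone (0.0355, and adjusted p = 0.749 with an estimated correlation); SAG29, at 1.83 ± 0.39, did not pass (0.0525). Pollen and anther markers had a median of -0.89 over 5 members and carpel, ovule and seed markers one of -0.11 over 5, neither called, but the pollen and anther markers, of another floral tissue, were called downward after quantile normalization (0.0405). In the other 11 lists no member passed by limma; adjusted over the list alone, 2 nutrient remobilisation genes were higher and 2 lower, 1 abscission gene was higher and 1 lower, 2 salicylic acid defence genes and 1 jasmonate signalling gene were higher and 1 flavonoid gene was lower. The median and mean of the flavonoid and anthocyanin list and of the salicylic acid defence list differed in sign, and no list moved on balance by fry.

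**Figure D2:**
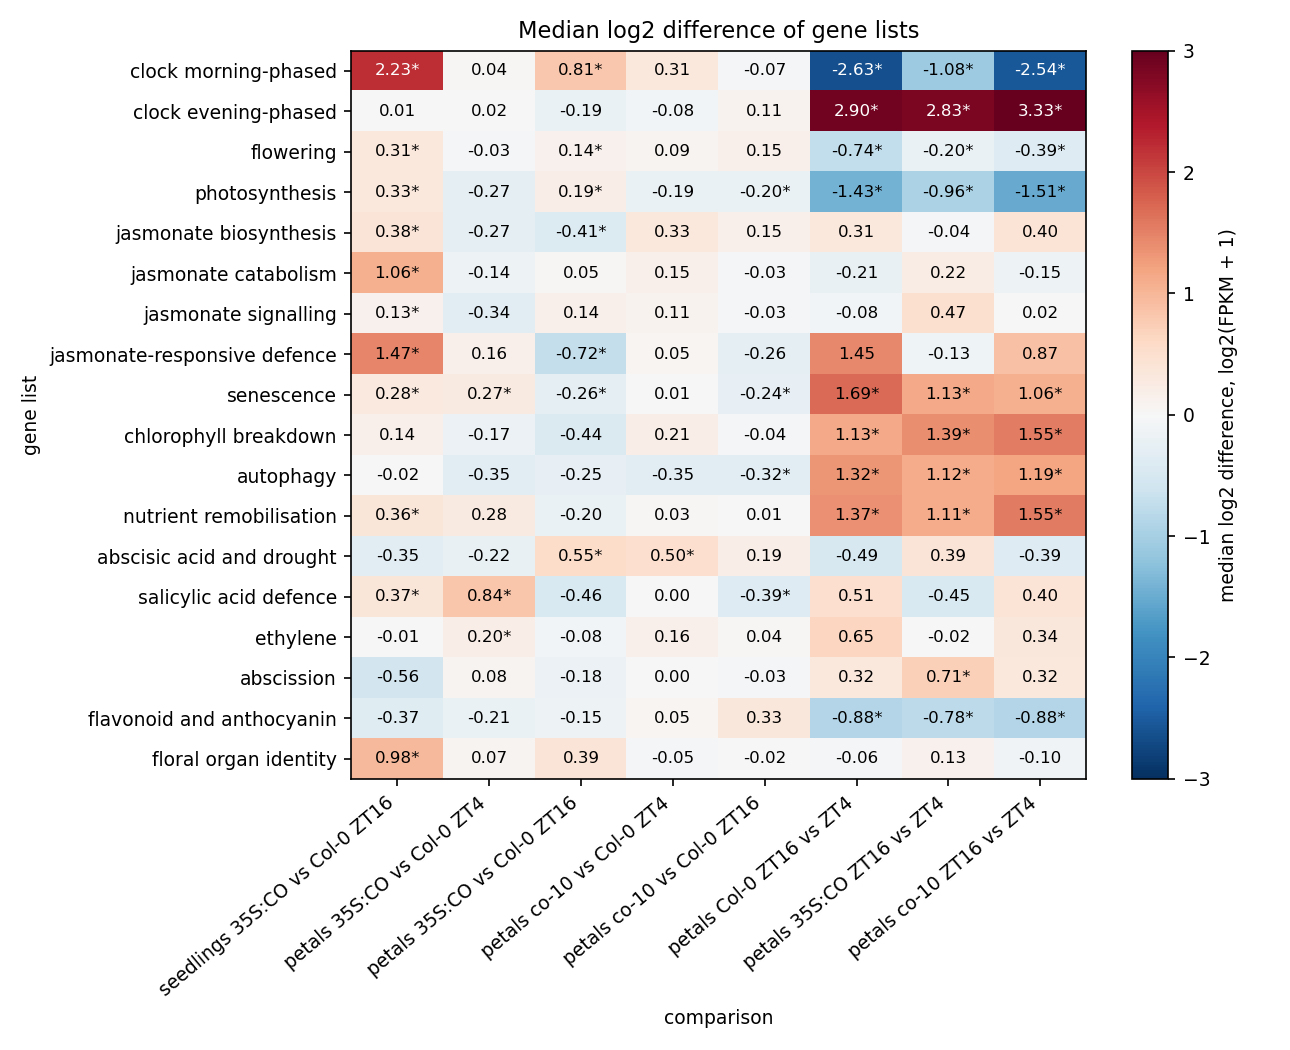
Median log2 difference, on log2(FPKM + 1), of the tested members of 18 gene lists in 8 comparisons, with a star where camera with its preset correlation gave an adjusted p under 0.05. Morning-phased clock genes stand at 2.23 in seedlings and 0.81 in petals at ZT16, and jasmonate-responsive defence genes at 1.47 and -0.72; no starred list passed with an estimated correlation.

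With 0.1 FPKM added, loci were sought that differed at least 2-fold between every 35S:CO library and every other library of the same tissue. Co-10 petals were among these others. By this measure 30 loci were higher in 35S:CO in both tissues. Only 3 loci were lower in both, a group on the upper arm of chromosome 5. They are LUL1 (760319 to 761840, minus strand), AT5G03285 (793514 to 793717) and ATMDAR2 (922048 to 924728, minus strand) and span 164.41 kb of TAIR10.1, far from CO on the same chromosome. AT5G03285, which was chosen after its values were seen, fell by 2.12 ± 0.14 in seedlings (adjusted p = 0.00308) and stood at -6.64 ± 0.67 in petals at ZT16 (6.21e-04); at ZT4 it stood at -4.12 ± 0.67 and did not pass (0.0611). The other 38 tested genes of the interval had a median of -0.13 in petals at ZT16 and -0.06 at ZT4, and the 41 tested in seedlings one of -0.04. Of these, AT5G03495 and AT5G03550, also chosen after their values were seen, were lower in petals at ZT16, at -3.13 ± 0.56 (0.0242) and -2.67 ± 0.52 (0.0341). In seedlings UBQ3 and AT5G03330 were lower, at -0.69 ± 0.08 (0.0133) and -0.55 ± 0.10 (0.0334), likewise chosen after their values were seen, and neither passed without either 35S:CO library. In co-10 the largest difference of the 3 loci from Col-0 petals at either time was 0.784 in size, without regard to its direction.

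**Figure D3:**
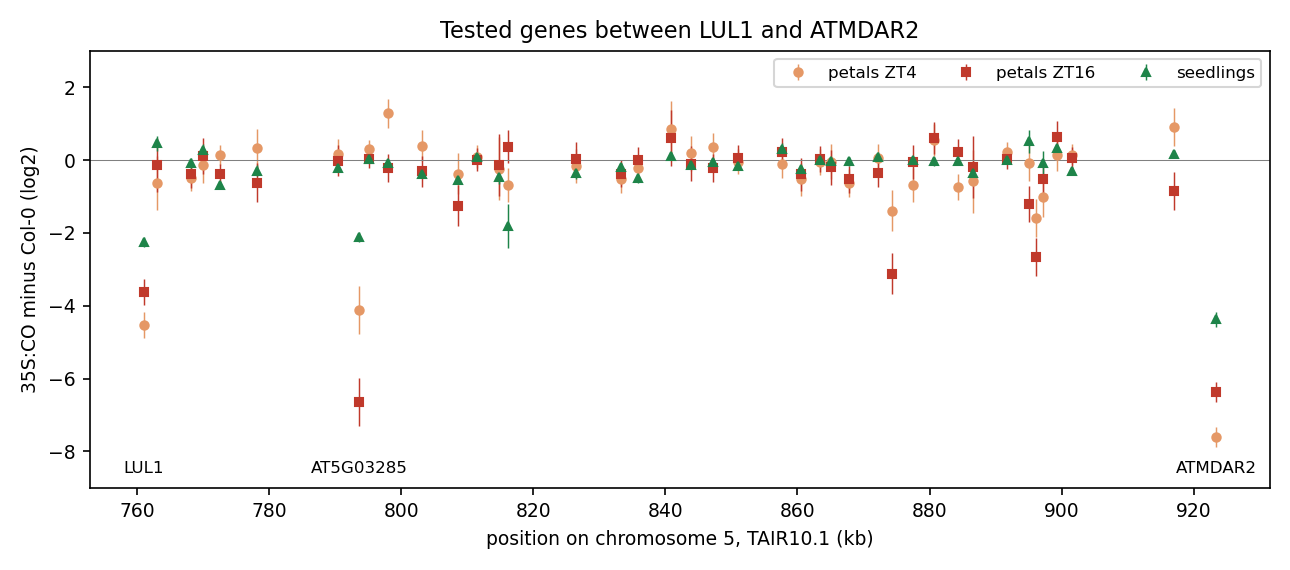
Log2 difference of 35S:CO from Col-0 (± SE) of each tested gene between LUL1 and ATMDAR2 against its position on chromosome 5 of TAIR10.1 in kb, in seedlings and in petals at both times. LUL1, AT5G03285 and ATMDAR2 lie below -2 in all 3 comparisons, and the other genes have medians between -0.13 and -0.04.

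The 35S:CO effects were compared between tissues and times by counting shared genes. Of 15943 genes tested in seedlings and in petals, 91 rose in both at ZT16, against 7.92 expected from the sizes of the 2 sets (Fisher's exact test across genes, p = 4.66e-79). They included FT, TSF, LHY, RVE8, GBSS1, LEA3, LEA4-5, LHCB2.3, PDX1.1, ARGAH2, the B-box genes BBX19, BBX30, BBX31 and BBX32, CDF3, a repressor of CO expression, and the nitrate reductase gene NIA2. Lower in both were 9 genes, against 2.30 expected (exact p = 3.72e-04), namely LUL1, AT5G03285, ATMDAR2, CCL, HIS1-3, SCRL7, NEK4, EXLB1 and SYTC. A further 7 went in opposite directions, against 10.05 expected. Between petals at ZT4 and ZT16, 13 genes rose at both times against 0.137 expected (exact p = 4.31e-25), among them CO, FT, LEA3, AMT1;2, HIPP22, MIPS2, PDX1.1, PDX1L4 and the catalase gene CAT2. ATMDAR2 and LUL1 fell at both times, where 0.00856 were expected (exact p = 2.39e-05). They and AT5G03285 are the 3 chromosome 5 loci above, whose fall was not told apart from a variant carried by the 35S:CO line. The overlaps of lower genes therefore do not by themselves show a shared response to CO. Genes are not independent replicates, so these p-values describe the overlap and not its certainty.

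For co-10 petals against Col-0 the question is what loss of CO changes. At ZT4, LpxC1, LpxC3, LpxC4 and LpxC5, of a family of lipid A-like synthesis genes, were listed at 0 in both co-10 libraries and stood at 7.37 ± 0.793 to 8.27 ± 0.824 FPKM in Col-0 (adjusted p = 0.00369 for each). The 4 loci share 98.5% or more of their 75-base stretches with each other, so they count as a single measurement. They were the 4 genes changed at ZT4 among 17876 tested, with 1430 at an unadjusted p under 0.05. Leaving out Col-0 ZT4 replicate 1 gave 0 genes by limma, Col-0 ZT4 replicate 2 gave 8, co-10 ZT4 replicate 2, the library of lowest estimated depth, gave 22, and co-10 ZT4 replicate 1 gave 685. None of the 4 passed without each library in turn. Camera called 1 list, abscisic acid and drought, upward, with a median of 0.50 over 19 members, 17 of them above 0, and none past the threshold by limma, over all genes or adjusted over the list alone (4.28e-04, and adjusted p = 0.363 with an estimated correlation). Jasmonate biosynthesis, at a median of 0.33, and senescence, at 0.01, held no member that passed. Adjusted over the list alone, 1 gene each of floral organ identity, flowering and nutrient remobilisation was lower. Of the 20 lists, 4 (abscission, flavonoid and anthocyanin, flowering and nutrient remobilisation) had a median and a mean of opposite sign.

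At ZT16 the co-10 petals differed from Col-0 in 4 genes, 2 higher and 2 lower. MIR2936, a microRNA locus, stood at 275 ± 24.6 FPKM in co-10 and 0.386 ± 0.0130 FPKM in Col-0 (adjusted p = 9.54e-04), and AT3G28820 at 67.6 ± 13.3 and 0.185 ± 0.262 FPKM (3.06e-04). SAG21, a small mitochondrial LEA protein gene named for its rise in senescing leaves, fell by 4.43 ± 0.44 (0.00372), from 733 ± 81.9 to 34.3 ± 13.7 FPKM. The chloroplast gene ATCG00020, which encodes the D1 protein of photosystem II, fell by 2.70 ± 0.34 (0.032). At an unadjusted p under 0.05 stood 393 genes, against 894 expected by chance. The count was 8 without co-10 ZT16 replicate 1 and 2 without Col-0 ZT16 replicate 2, and MIR2936 and AT3G28820 passed without each library in turn. Camera called 4 lists downward. Senescence had SAG21 lower and 29 that did not pass, with 3 lower adjusted over the list alone and a median of -0.24 (1.12e-07, and adjusted p = 0.567 with an estimated correlation); WRKY70, a regulator of defence and senescence, stood at -2.90 ± 0.63 and did not pass (0.497). Autophagy had a median of -0.32 with 13 of 14 members below 0 (6.15e-04, and adjusted p = 0.662 with an estimated correlation), salicylic acid defence one of -0.39 (0.00108, and adjusted p = 0.567 with an estimated correlation) and photosynthesis one of -0.20 (0.00214, adjusted p = 0.0569 after quantile normalization and 0.72 with an estimated correlation). In these 3 lists no member passed by limma, over all genes or adjusted over the list alone. In 5 lists that were not called the median, mean and test differed in sign: abscission, both clock lists, ethylene and nutrient remobilisation. Pollen and anther markers had a median of 0.41 and were not called (camera adjusted p = 0.114), but were called upward after quantile normalization (0.00983). No list moved on balance by fry at either time.

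Limma called no gene in opposite directions in 35S:CO and co-10 petals, but with 0.00358 (ZT4) and 0.0228 (ZT16) expected this decides nothing. AT3G28820 was higher than in Col-0 in both genotypes at ZT16, the only gene called in the same direction. The 2 comparisons share their Col-0 libraries, and the log2 differences correlated across genes at 0.334 at ZT4 and 0.371 at ZT16. Simulated groups without any difference, set against the same controls, gave 0.503 and 0.497.

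The series also sets 35S:CO directly against co-10. In petals at ZT4 the highest differences besides CO were those of FT at 5.71 ± 0.71 (adjusted p = 0.00745), LEA3 at 4.57 ± 0.47, AMT1;2 at 3.50 ± 0.36 and HIPP22 at 2.82 ± 0.38, and the 4 LpxC loci, listed at 0 in co-10. ATMDAR2, listed at 0 in 35S:CO, was lower (3.14e-07), as were LUL1 at -4.49 ± 0.36 and the myrosinase genes TGG2 and TGG1, of glucosinolate defence, at -3.72 ± 0.44 and -3.09 ± 0.53. P5CS1, of proline synthesis, was lower at -2.51 ± 0.43 and ABF3 at -2.20 ± 0.35, and PR2, a glucanase of salicylic acid defence, rose by 2.32 ± 0.39 (0.0395). Of 17876 genes, 57 changed, 40 higher and 17 lower. The count was 12 without 35S:CO replicate 1, 31 without 35S:CO replicate 2 and 713 without co-10 replicate 1, all of ZT4, and 7 of 17 named genes passed without each library in turn. Salicylic acid defence was called upward, with PR2 higher and 11 not passing, and 6 higher adjusted over the list alone (0.00193, and adjusted p = 0.579 with an estimated correlation). Abscisic acid and drought was called downward, with 2 lower and 17 not passing, and 5 lower adjusted over the list alone (1.35e-04, and adjusted p = 0.286 with an estimated correlation). Jasmonate biosynthesis and signalling were called downward with no member past the threshold by limma, at medians of -0.37 and -0.32 and with 2 and 0 lower adjusted over the list alone (0.0011 and 0.0104, and adjusted p = 0.604 and 0.655 with an estimated correlation). Signalling was not called after quantile normalization (0.133). The median, mean and test of 6 lists that were not called differed in sign: abscission, autophagy, morning-phased clock, ethylene, flowering and jasmonate-responsive defence.

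At ZT16 the difference between 35S:CO and co-10 petals again held FT at 7.99 ± 0.71 (adjusted p = 3.34e-04), LEA3 at 7.15 ± 0.47, LHCB2.3 at 5.77 ± 0.51, AMT1;2 at 5.02 ± 0.36, ARGAH2 at 4.90 ± 0.60 and BBX30, a small B-box protein gene, at 4.28 ± 0.27. Lower were MIR2936 at -7.74 ± 0.63, the drought-inducible histone H1 gene HIS1-3 at -4.33 ± 0.44, LUL1 at -3.37 ± 0.36 and TGG2 at -3.27 ± 0.44. ATMDAR2, again listed at 0 in 35S:CO, was lower too, and COR15A was higher at 3.22 ± 0.41. LOX4, a lipoxygenase of jasmonate synthesis, fell by 2.21 ± 0.40 (0.0273), SAG21 rose by 3.12 ± 0.44 and SAG29 by 2.42 ± 0.39, and the protease gene ALPHA-VPE fell by 2.89 ± 0.52. Of 17876 genes, 166 changed, 122 higher and 44 lower. The count was 30 without 35S:CO replicate 1, 48 without 35S:CO replicate 2, 448 without co-10 replicate 1 and 64 without co-10 replicate 2, all of ZT16, and 11 of 29 named genes passed without each library in turn. Upward lists were morning-phased clock with 2 of 10 higher and 4 adjusted over the list alone (1.30e-08, and adjusted p = 0.41 with an estimated correlation) and flowering with 3 of 17 higher and 3 adjusted over the list alone (0.0126, and adjusted p = 0.41 with an estimated correlation). Photosynthesis had RCA and RBCS3B of 40 higher and 5 adjusted over the list alone (4.95e-08, and adjusted p = 0.663 with an estimated correlation). RBCS2B, at 2.93 ± 0.60, did not pass (0.0507). Floral organ identity was also called upward, with 0 of 11 past the threshold by limma and 2 adjusted over the list alone (0.0126, and adjusted p = 0.586 with an estimated correlation). Jasmonate biosynthesis was called downward, with LOX4 of 16 lower, 5 lower adjusted over the list alone and a median of -0.64 (2.36e-04, and adjusted p = 0.422 with an estimated correlation). Pollen and anther markers were called downward too (0.00473, and adjusted p = 0.422 with an estimated correlation), with median -1.30 over 5 members. None passed by limma and 4 were lower adjusted over the list alone. Anther tissue in the petals was not separated from genotype at ZT16. Jasmonate signalling, nutrient remobilisation and senescence, not called, had a median, mean and test that differed in sign, and by fry no list moved on balance at either time.

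Time of day was compared within each genotype of petals, and in Col-0 the evening against the morning set clock, photosynthesis and senescence genes apart. The labels give no stage or age of the petals, so stage was not separated from time of day or genotype. At ZT16 the evening-phased ELF4 was higher by 5.13 ± 0.47 (adjusted p = 1.02e-04), ELF3 by 3.77 ± 0.39 and TOC1 by 2.82 ± 0.32, and the morning-phased LNK2 and CCA1 were lower, at -4.92 ± 0.36 (3.34e-05) and -3.65 ± 0.37. Senescence regulators and enzymes rose, WRKY75 by 5.93 ± 0.57, RNS1 by 5.83 ± 0.61, SEN1 by 4.33 ± 0.65 and the cysteine protease gene CEP1 by 3.97 ± 0.35. The protease inhibitor gene KTI1 rose by 6.44 ± 0.62, and LHCB2.1, COR15A and STH, a B-box gene, were lower at -6.59 ± 0.43, -6.24 ± 0.41 and -6.34 ± 0.46. Of 17876 genes, 2747 changed, 1530 higher and 1217 lower. The count was 1189 without ZT4 replicate 1, 1281 without ZT16 replicate 1, 1807 without ZT4 replicate 2 and 1455 without ZT16 replicate 2, and 66 of 117 named genes passed without each library in turn.

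Of the lists in Col-0 petals, senescence had 17 of 30 higher at ZT16 and 13 that did not pass, with 23 adjusted over the list alone (camera adjusted p = 2.13e-10, and adjusted p = 0.177 with an estimated correlation). Nutrient remobilisation had 11 of 20 higher, with 14 adjusted over the list alone (3.88e-09, and adjusted p = 0.143 with an estimated correlation), among them the sugar carrier STP13 at 3.37 ± 0.36 and the glutamine synthetase GLN1;1 at 3.39 ± 0.37. Autophagy had 7 of 14 higher, with 10 adjusted over the list alone (4.18e-06, and adjusted p = 0.216 with an estimated correlation), ATG7 by 2.90 ± 0.34. Chlorophyll breakdown had 3 of 7 higher and 1 lower, with 5 and 1 adjusted over the list alone (0.00965, and adjusted p = 0.226 with an estimated correlation). Evening-phased clock genes had 8 of 11 higher, with 9 higher and 1 lower adjusted over the list alone (1.81e-07, and adjusted p = 0.143 with an estimated correlation). Morning-phased ones had 7 of 10 lower and RVE2, a relative of CCA1, higher by 4.13 ± 0.58, with 1 and 8 adjusted over the list alone (7.39e-07, and adjusted p = 0.179 with an estimated correlation). Photosynthesis had 19 of 40 lower, with 28 adjusted over the list alone (6.74e-14, and adjusted p = 0.316 with an estimated correlation). Flowering had 7 of 17 lower, also adjusted over the list alone (0.00142, and adjusted p = 0.143 with an estimated correlation), and flavonoid and anthocyanin 1 higher and 2 lower of 13, with 1 and 5 adjusted over the list alone (0.0225, and adjusted p = 0.316 with an estimated correlation). The flowering members that fell included GBSS1 and the CO relatives COL1 and COL2. Jasmonate lists were not called: biosynthesis had LOX4, KAT2 and ACX1 of 16 higher, signalling 3 higher and 1 lower of 24, defence 4 higher and 1 lower of 12 and catabolism 1 and 1 of 8, with 3 and 0, 3 and 2, 6 and 1, and 2 and 1 adjusted over the list alone. MYB24 and MYB57, jasmonate-regulated genes of petal and stamen growth, went opposite ways, at 2.89 ± 0.34 and -4.36 ± 0.45, and CLH1, a chlorophyllase-like gene, fell by 4.76 ± 0.47. Ethylene had 3 higher and 1 lower of 14, with 5 and 2 adjusted over the list alone, and abscission 3 higher of 11, also adjusted over the list alone. Abscisic acid and drought had 2 and 2 of 19, with 3 and 2, salicylic acid defence 2 higher of 12, with 3, floral organ identity 1 lower of 11, and the carpel, ovule and seed markers 1 higher of 5, both unchanged when adjusted over the list alone. Pollen and anther markers had a median of 1.01 with none past the threshold by limma and were not called (0.0509), but were called upward after quantile normalization (0.0298) and rescaling (0.0452). By fry 10 of 20 lists moved on balance, these 9 and abscission.

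Between the times in 35S:CO petals, the copine gene BON1 rose by 5.12 ± 0.69 (adjusted p = 0.00422), RNS1 by 4.60 ± 0.61, UMAMIT10, of an amino acid transporter family, by 4.38 ± 0.32, ELF4 by 4.18 ± 0.47 and TOC1 by 2.75 ± 0.32. Lower were LHCB2.2 at -3.91 ± 0.45, LNK2 at -3.90 ± 0.36, CLH1 at -3.85 ± 0.47 and CCA1 at -3.31 ± 0.37. MYB24 rose by 3.24 ± 0.34, and CO stood at 0.35 ± 0.33 and did not pass. Of 17876 genes, 757 changed, 540 higher and 217 lower, and 566 and 430 after quantile normalization or 1774 and 1324 with only the 4 libraries compared. Whether fewer genes pass here than in Col-0 and co-10 depends on the setting: with only the 4 libraries compared 3098 passed, against 3077 and 212, and with array weights, chosen after seeing the data, 3293, against 3124 and 888. The count was 44 without ZT4 replicate 1, 39 without ZT16 replicate 1, 288 without ZT4 replicate 2 and 91 without ZT16 replicate 2, and 12 of 62 named genes passed without each library in turn. Evening-phased clock genes had 9 of 11 higher, with 9 higher and 1 lower adjusted over the list alone (2.19e-09, and adjusted p = 0.178 with an estimated correlation). Morning-phased ones had 1 higher and 4 lower of 10, with 1 and 6 (4.32e-05, and adjusted p = 0.225 with an estimated correlation). Senescence had 8 of 30 higher, with 18 adjusted over the list alone (3.51e-08, and adjusted p = 0.225 with an estimated correlation). Nutrient remobilisation had 9 of 20, with 10 (4.63e-09, and adjusted p = 0.178 with an estimated correlation), and autophagy 3 of 14, with 11 (1.48e-08, and adjusted p = 0.178 with an estimated correlation). Chlorophyll breakdown had 2 of 7, with 5 (6.37e-04, and adjusted p = 0.178 with an estimated correlation) and abscission 1 of 11, with 1 (0.0336, and adjusted p = 0.247 with an estimated correlation). Photosynthesis had 6 of 40 lower, with 11 adjusted over the list alone (7.70e-14, and adjusted p = 0.269 with an estimated correlation). Flowering had 1 higher and 3 lower of 17, with 2 and 6 (0.0336, adjusted p = 0.0694 after quantile normalization and 0.225 with an estimated correlation), and flavonoid and anthocyanin 1 of 13 lower, with 2 (0.0113, and adjusted p = 0.254 with an estimated correlation). The other lists were not called, and ethylene, floral organ identity, jasmonate biosynthesis and jasmonate catabolism had a median, mean and test that differed in sign. By fry 8 of 20 lists moved on balance.

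In co-10 petals UMAMIT10 rose by 6.26 ± 0.32 (adjusted p = 6.70e-06), ELF4 by 6.05 ± 0.47, RNS1 by 5.75 ± 0.61 and the nitrilase gene NIT3 by 5.69 ± 0.86 from ZT4 to ZT16. COR15A was lower at -6.66 ± 0.41, LHCB2.1 at -6.09 ± 0.43, CDF3 at -5.62 ± 0.42, LNK2 at -5.01 ± 0.36 and CCA1 at -4.56 ± 0.37. SAG21 fell by 3.82 ± 0.44, whereas it rose by 1.54 ± 0.44 in Col-0, and JMT fell by 2.12 ± 0.41. Of 17876 genes, 2379 changed, 1522 higher and 857 lower. The excess of higher genes depends on scaling and libraries: it was 1220 and 1205 after quantile normalization, when the median of all genes went from 0.21 to 0.03, 106 and 106 with only the 4 libraries compared and 1300 and 1587 without ZT16 replicate 1. The count was 1421 without ZT4 replicate 2 and 896 without ZT16 replicate 2, and 62 of 104 named genes passed without each library in turn. Senescence had 12 of 30 higher and SAG21 lower, with 17 and 2 adjusted over the list alone (8.24e-05, and adjusted p = 0.366 with an estimated correlation). Nutrient remobilisation had 10 of 20 higher, with 15 (1.30e-07, and adjusted p = 0.151 with an estimated correlation), autophagy 5 of 14, with 10 (5.81e-05, and adjusted p = 0.3 with an estimated correlation) and chlorophyll breakdown 3 higher and 1 lower of 7, with 5 and 1 (0.0499, and adjusted p = 0.366 with an estimated correlation). Evening-phased clock genes had 8 of 11 higher, with 9 adjusted over the list alone (4.52e-07, and adjusted p = 0.151 with an estimated correlation). Morning-phased ones had 1 higher and 7 lower of 10, with 1 and 9 (9.79e-09, and adjusted p = 0.151 with an estimated correlation). Photosynthesis had 21 of 40 lower, with 29 adjusted over the list alone (3.27e-20, and adjusted p = 0.3 with an estimated correlation). Flowering had 5 of 17 lower, with 5 (0.00364, and adjusted p = 0.151 with an estimated correlation), and flavonoid and anthocyanin 2 of 13 lower, with 3 (0.0389, and adjusted p = 0.37 with an estimated correlation). Jasmonate signalling, salicylic acid defence and the carpel, ovule and seed markers, not called, had a median, mean and test that differed in sign, and 9 of 20 lists moved on balance by fry. Over the 2379 genes that changed in co-10, the median ratio to the co-10 difference was 0.948 in Col-0 and 0.558 in 35S:CO.

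**Figure D4:**
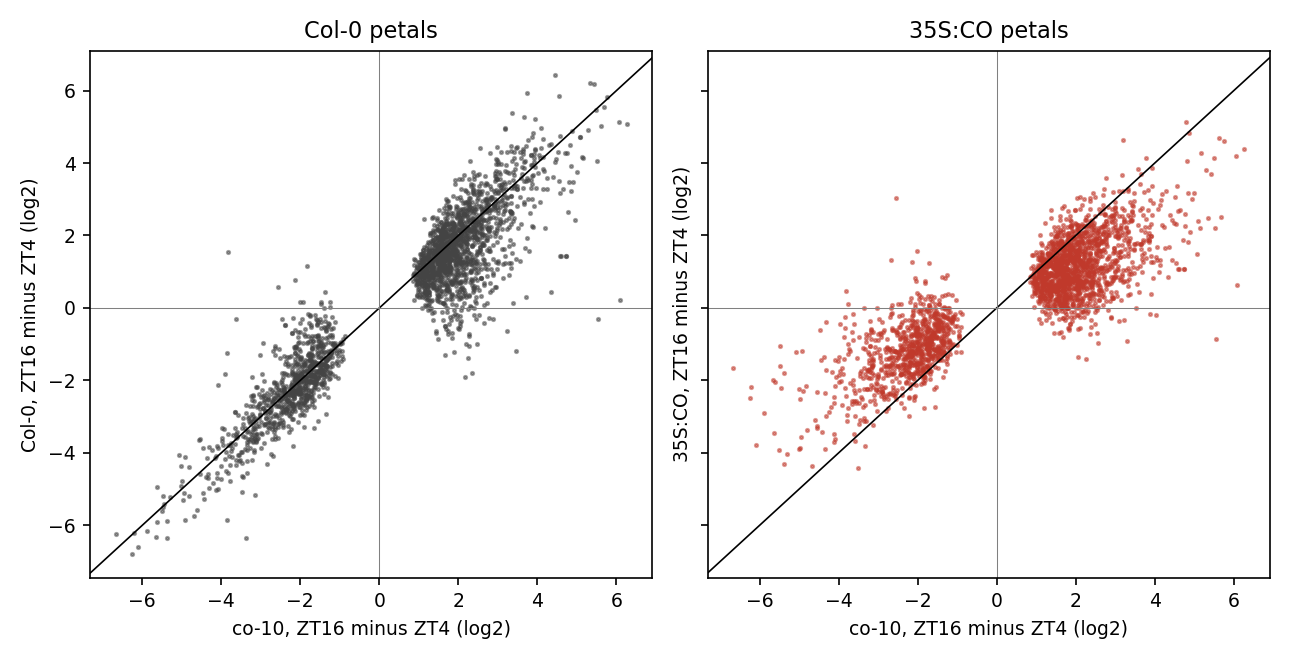
Log2 difference of ZT16 from ZT4 in Col-0 (left) and 35S:CO (right) petals against that in co-10 petals, for the 2379 genes (points) that changed in co-10, with the line of equal differences. The median ratio to co-10 is 0.948 in Col-0 and 0.558 in 35S:CO.

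The interaction with time asks whether the genotype difference itself changed between ZT4 and ZT16. For 35S:CO it rose for 4 genes, which were the only genes called of 17876: CBL6 by 5.59 ± 0.38 (adjusted p = 2.75e-04), COR15A by 4.58 ± 0.58 (0.0335), UP6 by 3.97 ± 0.49 (0.0335) and BBX30 by 3.88 ± 0.39 (0.00656). CBL6 and UP6 are listed at 0 in Col-0 at ZT16, so the sizes of these 2 depend on the added 1 FPKM. At an unadjusted p under 0.05 stood 1202 genes. The count was 1 without Col-0 ZT4 replicate 1, without 35S:CO ZT4 replicate 1, without 35S:CO ZT16 replicate 1 or without 35S:CO ZT16 replicate 2, 2 without Col-0 ZT16 replicate 2 and 10 without co-10 ZT4 replicate 2, and CBL6 alone passed without each library in turn. Camera called 5 lists upward, among them morning-phased clock with a median of 1.07 (2.07e-04, and adjusted p = 0.394 with an estimated correlation) and flowering with 0.60 (0.00955, and adjusted p = 0.394 with an estimated correlation). Also called were photosynthesis with 0.54 (0.0016, and adjusted p = 0.655 with an estimated correlation), abscisic acid and drought with 0.51 (0.0246, and adjusted p = 0.394 with an estimated correlation) and jasmonate signalling with 0.32 (0.0279, adjusted p = 0.0584 after quantile normalization and 0.515 with an estimated correlation). It called 5 downward, among them jasmonate-responsive defence with a median of -1.33 (0.011, and adjusted p = 0.394 with an estimated correlation) and salicylic acid defence with -0.85 (4.38e-04, and adjusted p = 0.394 with an estimated correlation). The others were ethylene with -0.54 (0.00976, and adjusted p = 0.445 with an estimated correlation), nutrient remobilisation with -0.45 (0.0364, and adjusted p = 0.561 with an estimated correlation) and senescence with -0.36 (3.62e-04, and adjusted p = 0.445 with an estimated correlation). Pollen and anther markers had a median of -0.56 and were not called (0.0705), but were called downward after quantile normalization (0.00954) and rescaling (0.0456). COR15A was the only member of these lists called over all genes; adjusted over the list alone, 3 abscisic acid and drought genes, 2 morning-phased clock genes, 1 jasmonate signalling gene and 1 photosynthesis gene were higher and 6 senescence genes were lower.

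For co-10 the interaction called 4 of 17876 genes, 3 higher and 1 lower, with 792 at an unadjusted p under 0.05. AT3G28820 rose (adjusted p = 0.0108), as did LpxC4 and LpxC3 (0.0455 each), which are listed at 0 in co-10 at ZT4 and share all their stretches, and SAG21 fell by 5.36 ± 0.62 (0.0259). The count was 0 by limma without Col-0 ZT4 replicate 1, Col-0 ZT16 replicate 1, Col-0 ZT16 replicate 2 or co-10 ZT16 replicate 1, and 294 without co-10 ZT4 replicate 1. Senescence was the 1 list called, downward, with SAG21 lower, 29 not passing, 2 lower adjusted over the list alone and a median of -0.38 (9.93e-05, and adjusted p = 0.706 with an estimated correlation). The median, mean and test differed in sign for abscission in both interactions, for autophagy and chlorophyll breakdown in that of 35S:CO and for nutrient remobilisation and photosynthesis in that of co-10. By fry no list moved on balance in either interaction.

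The interaction with tissue asks whether 35S:CO differs from Col-0 at ZT16 to another degree in petals than in seedlings. JMT was lower by -3.37 ± 0.56 (adjusted p = 0.0133), LOX4 by -2.80 ± 0.50 (0.0191) and JAZ9 by -2.09 ± 0.37 (0.019), so these differences were smaller or more negative in petals, and JAZ4 was higher by 0.80 ± 0.13 (0.0139). SAG13, DIN2 and SAG29 were lower by -4.10 ± 0.74, -3.57 ± 0.72 and -2.78 ± 0.53. CBL6 was higher by 5.49 ± 0.31 (1.05e-05), AMT1;2 by 3.99 ± 0.42, PDX1.1 by 3.57 ± 0.48 and RCA by 2.36 ± 0.42, and SIB2, a sigma factor-binding protein gene, was lower by -4.76 ± 0.54, CDA1 by -4.57 ± 0.52 and THI2.2 by -4.36 ± 0.30. For THI2.2, CDA1 and JAZ4 the value is close to the seedling difference with its sign turned, which leaves little difference in petals. Of 21200 genes tested over all 16 libraries, 15943 were also tested in both the seedling fit and the petal fit, so a called gene need not be expressed in petals. In this interaction 329 genes changed, 163 higher and 166 lower. Both that number and the direction holding more genes depended on the setting, as given in the section on processing. The count was 187 without seedling Col-0 replicate 1, 121 and 133 without seedling 35S:CO replicate 1 and 2, 188 without petal Col-0 ZT16 replicate 1, and 164 and 154 without petal 35S:CO ZT16 replicate 1 and 2. Of 28 named genes that passed, 9 did so without each library in turn, namely CBL6, AMT1;2, PDX1.1, PELPK1, PAL4, SIB2, CDA1, THI2.2 and NATA1.

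Camera called 10 lists downward in the interaction with tissue. Jasmonate-responsive defence had a median of -2.28, with none of 14 past the threshold by limma and 7 lower adjusted over the list alone (camera adjusted p = 4.58e-09, and adjusted p = 0.0879 with an estimated correlation). Its vegetative storage protein genes VSP1 and VSP2 stood at -3.47 ± 0.77 and -3.40 ± 0.89 and did not pass. Jasmonate biosynthesis had 2 of 16 lower, 4 adjusted over the list alone and no member above 0 (1.45e-08, and adjusted p = 0.165 with an estimated correlation). Jasmonate catabolism had a median of -0.54, or -0.92 after quantile normalization, with none of 9 past the threshold (0.018, and adjusted p = 0.306 with an estimated correlation). Senescence had 3 of 31 lower, with 8 adjusted over the list alone (6.14e-08, and adjusted p = 0.306 with an estimated correlation). Nutrient remobilisation had ICL, of the glyoxylate cycle, higher by 1.19 ± 0.21 and 20 not passing, with 1 and 3 (0.0114, and adjusted p = 0.306 with an estimated correlation). Morning-phased clock genes had a median of -0.83, with 3 lower adjusted over the list alone and -1.47 after quantile normalization (0.00546, and adjusted p = 0.306 with an estimated correlation), and evening-phased ones -0.43, with 1 (0.0214, and adjusted p = 0.306 with an estimated correlation). Floral organ identity had SEP1 lower by -1.96 ± 0.36 and 10 not passing, with 2 adjusted over the list alone (0.018, and adjusted p = 0.306 with an estimated correlation). After quantile normalization this list was not called (0.223) and its median went from -0.56 to 0.07. Salicylic acid defence had a median of -0.61 (0.018, and adjusted p = 0.306 with an estimated correlation) and the pollen and anther markers one of -1.12 over 5 members, with 1 lower adjusted over the list alone (0.0114, and adjusted p = 0.306 with an estimated correlation). Abscisic acid and drought was called upward, with ERD10, a dehydrin, higher by 1.91 ± 0.37, ABF3 lower by -2.20 ± 0.37 and 18 not passing, and 4 and 1 adjusted over the list alone (0.018, and adjusted p = 0.306 with an estimated correlation). Photosynthesis, not called, had RCA higher and LHCB2.2 lower by -2.86 ± 0.60, with 38 not passing and 4 and 4 adjusted over the list alone, and jasmonate signalling had JAZ4 higher and JAZ9 lower, with 24 not passing and 2 and 2. Root markers had a median of 0.12 over 8 and carpel, ovule and seed markers one of -0.41 over 6, and neither was called. Ethylene, also not called, had a median and a mean of opposite sign. By fry jasmonate biosynthesis and jasmonate-responsive defence moved on balance, at adjusted p = 0.0402 and 0.0319.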

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

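The results here are differences between groups that were themselves tested, as interactions of genotype with time or with tissue. The tests of the 3 chromosome 5 loci and the 2 ratios of gene numbers between 35S:CO and co-10 were chosen only after the result was seen, as was the range over left-out libraries as the spread of the time ratios. Groups of 2 libraries are too small for a test of single outlying libraries.

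The 35S:CO difference in petals changed between ZT4 and ZT16 for 4 genes by limma, CBL6 by 5.59, COR15A by 4.58, UP6 by 3.97 and BBX30 by 3.88, and camera called 10 lists, of which 0 were called with an estimated correlation (adjusted p = 0.394 to 0.655) and 0 by fry. The co-10 difference changed between the times for 4 genes, AT3G28820 by 5.86, LpxC4 by 3.30, LpxC3 by 3.28 and SAG21 by -5.36, and camera called 1 list, senescence, which was not called with an estimated correlation (adjusted p = 0.706) or by fry. AT3G28820 was listed at 0 in Col-0 and co-10 petals at ZT4, and LpxC3 and LpxC4 in co-10 at ZT4, so their values depend on the added 1 FPKM. Without co-10 ZT4 replicate 1, 294 genes were called in the co-10 interaction, and without Col-0 ZT4 replicate 1, Col-0 ZT16 replicate 1, Col-0 ZT16 replicate 2 or co-10 ZT16 replicate 1 it was 0 by limma. There were 792 genes at an unadjusted p under 0.05 when all libraries were used. Counts for 35S:CO without single libraries are given above.

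The 35S:CO difference at ZT16 was not the same in petals as in seedlings for 329 genes. Camera called 11 lists, of which 0 were called with an estimated correlation (adjusted p = 0.0879 to 0.306) and 2 by fry, and floral organ identity was not called after quantile normalization. Petal minus seedling differences above 0 among the named genes were those of CBL6 (5.49), AMT1;2 (3.99), PDX1.1 (3.57), PELPK1 (3.53), GLDP1 (3.48), PAL4 (3.43), IAA14 (3.31), PHOT1 (3.30), RCA (2.36), CO (2.31), ERD10 (1.91), ICL (1.19) and JAZ4 (0.80). Those below 0 were SIB2 (-4.76), CDA1 (-4.57), KTI1 (-4.42), NIT2 (-4.41), THI2.2 (-4.36), ZF14 (-4.27), SAG13 (-4.10), NATA1 (-4.003), DIN2 (-3.57), JMT (-3.37), LHCB2.2 (-2.86), LOX4 (-2.80), SAG29 (-2.78), ABF3 (-2.20), JAZ9 (-2.09) and SEP1 (-1.96). Leaving out any compared library lowered the count. Tissue differs here together with age and depth, and no technical explanation was tested for this difference.

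The lower levels of LUL1, AT5G03285 and ATMDAR2 in every 35S:CO library of both tissues were weighed against 3 explanations. A single deletion is argued against, because the other 38 tested genes between the outer loci had a median difference of -0.133 in petals at ZT16, with an interquartile range of -0.391 to 0.0350 and only 2 called lower there. Unlinked genes that respond to CO are argued against as well, because draws of 3 loci from the 12493 that could have passed lay within as short a span in 1 of 100000 cases, a share of 2.00e-05 with the observed loci counted. A variant or insertion carried by the 35S:CO line in this region cannot be told apart from a local response to CO, which was not tested, because no reads that could show one were used here. In co-10 petals the largest difference of the 3 loci from Col-0 was 0.784 in size, which decides nothing, since 84.2% of random draws of 3 loci stayed within 2-fold there as well. The co-10 libraries also took part in the choice of these loci.

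The time difference was smaller in 35S:CO petals than in co-10, with a median ratio of 0.558 over the 2379 genes called in co-10 (0.495 to 0.648 when each of the 8 libraries in it was left out in turn), against 0.948 in Col-0. Rescaling without ribosomal and organelle loci gave 0.560 (0.493 to 0.643) but shifts rises and falls alike, so it does not test scaling. Compression of low genes as the whole cause is argued against narrowly. Genes with a mean of at least 20 FPKM gave 0.674 (0.588 to 0.796), under the bound of 0.8. Collection of the 35S:CO petals nearer in time cannot be told apart, because the ratio over 8 evening-phased clock genes was 0.839 with a range of 0.743 to 0.894 that spans that bound, while 8 morning-phased ones gave 0.596 (0.536 to 0.671). For the genotype as a whole, the 1522 genes higher at ZT16 in co-10 had a fry p = 0.0561 in the 35S:CO by time interaction of the petal fit (n = 12 libraries, 2 per group) and a median of -0.44, and those lower at ZT16 a fry p = 0.0229 and a median of 1.00. Over 20 random orders of the libraries, on which fry depends, the former p ran from 0.0490 to 0.0598 and was under 0.05 in 2 orders, so the genotype could contribute but cannot be told apart from the open explanations, and the 2379 genes were chosen by their change in co-10.

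Only 4 genes were called in co-10 petals at each time, and this number was weighed against the power of the comparison. It also moved with the processing, as given in the next section. Col-0 petals held little CO transcript, 0.405 FPKM at ZT4 and 0.114 FPKM at ZT16, against 0.143 and 0.113 FPKM in co-10. How far this accounts for the small number of genes was not tested. The spread between petal libraries may hide differences, since in simulated petal data 0.606% of genes changed by 1 on the log2 scale were called, with genes of low level not among those changed. The shallow library may do so at ZT4, where leaving out co-10 ZT4 replicate 2 gave 22 genes, although leaving out co-10 ZT4 replicate 1, and so keeping the shallow one, gave 685, and Col-0 ZT4 replicate 1 and 2 gave 0 (by limma) and 8. At ZT16, 1806 genes had an unadjusted p under 0.05 in 35S:CO and 393 in co-10, a ratio of 4.60, with 894 expected by chance. This argues against a difference of co-10 from Col-0 as wide as that of 35S:CO. The co-10 number lies below chance, so the p-values there are not well calibrated and the ratio overstates the contrast. At ZT4 that ratio was 0.776, so there the tables leave a difference as wide as that of 35S:CO open.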

How the results depend on the processing

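Array weights, a mean of at least 5 FPKM, rescaling without ribosomal and organelle loci, fits without co-10 ZT4 replicate 2 for other comparisons, quantile normalization of the list tests and random library orders in fry were chosen after seeing the data, and the other settings were chosen before. Settings that need counts were not run on FPKM, namely other size factors, upper-quartile factors, a count-model test and voom weights.

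The rise of CO in 35S:CO kept its direction and its side of the threshold under the alternatives run. When each library of the groups compared was left out in turn, with the lone library of a group assumed to vary like the other groups, it ranged from 6.63 to 6.72 in seedlings, 8.02 to 8.64 in petals at ZT4 and 8.84 to 9.14 at ZT16. The counts of genes called then ranged from 54 to 3129 in seedlings, 7 to 23 (ZT4) and 48 to 82 (ZT16) for 35S:CO petals, 0 to 685 and 2 to 8 for co-10, 12 to 713 and 30 to 448 for 35S:CO against co-10, 1189 to 1807 for time in Col-0, 39 to 288 in 35S:CO and 896 to 3138 in co-10. For the interactions the ranges were 1 to 5 for 35S:CO with time, 0 to 294 for co-10 with time and 121 to 235 with tissue.

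The following counts moved by more than 1.5 times, and the cause was not tested. With all 16 libraries in one fit the counts were 696 in seedlings, 86 (ZT4) and 464 (ZT16) for 35S:CO petals, 64 and 15 for co-10, 280 and 427 for 35S:CO against co-10, 1529 and 3755 for time in 35S:CO and in co-10, and 54 and 24 for the interactions of 35S:CO and of co-10 with time. With only the 4 libraries compared they were 39 and 314 for 35S:CO, 1 and 8 for co-10, 2 and 26 for 35S:CO against co-10, and 3098 and 212 for time in 35S:CO and in co-10. A pseudocount of 0.1 gave 121 for 35S:CO at ZT16, 23 and 8 for co-10 at ZT4 and ZT16, 102 for 35S:CO against co-10 at ZT16, 461 for time in 35S:CO, 14 for co-10 with time and 125 for the interaction with tissue. No filter gave 7 and 9 for co-10, 36 for 35S:CO against co-10 at ZT4, 9 for co-10 with time and 883 for tissue. Quantile normalization gave 32 for 35S:CO at ZT4, 9 for co-10 at ZT16 and 2 for co-10 with time.

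Array weights gave 34 and 626 for 35S:CO, 29 for 35S:CO against co-10 at ZT4, 3293 and 888 for time in 35S:CO and in co-10, 66 and 0 (by limma) for the interactions of 35S:CO and of co-10 with time and 886 for tissue. A mean of at least 5 FPKM, with fewer genes tested, gave 37 for 35S:CO against co-10 at ZT4, 8 for 35S:CO with time and 67 for tissue. The 2-fold limit left 739 genes in seedlings. Fits without co-10 ZT4 replicate 2 gave 10 for 35S:CO with time, and within that factor 27 and 247 for 35S:CO at ZT4 and ZT16, 4 for co-10 and 197 for 35S:CO against co-10 at ZT16, 3310 and 1072 for time in Col-0 and in 35S:CO, and, in the fit over the other 15 libraries, 334 for tissue. A replicate block gave 1178 in seedlings, 7 for 35S:CO with time and 2 for co-10 with time. The replicate numbers show no uniform pairing: deviations of equally numbered replicates correlated across genes, which are not independent replicates, at -0.302 to 0.228 over 15 pairs of petal groups and at -0.0164 in seedlings.

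Of the 86 lists called by camera with its preset correlation, 0 were called with an estimated correlation. By fry 35 lists were called in all, 30 of them among the 86, and over 20 random library orders the number ran from 35 to 37. Quantile normalization kept 81 of the 86 and rescaling 86. The 5 lists not called after quantile normalization were photosynthesis in co-10 at ZT16, jasmonate signalling in 35S:CO against co-10 at ZT4 and in the interaction of 35S:CO with time, flowering for time in 35S:CO and floral organ identity in the interaction with tissue. Not called before, 8 lists were called after quantile normalization and 4 after rescaling, 5 and 2 of them the pollen and anther markers. For the named genes, 5686 of 7089 values over 534 results kept direction and side of the threshold, 1370 no longer passed, 33 newly passed and 0 reversed. With a 2-fold limit 81 genes were higher and 6 lower in both seedlings and petals at ZT16. Petals had 13675 to 16526 loci at 1 FPKM or more and seedlings 18664 to 19033, and tissue, age and depth are not separated here. The direction holding more genes also turned in other comparisons: time in Col-0 gave 1497 higher and 1580 lower with only the 4 libraries compared, 35S:CO against co-10 at ZT4 gave 15 and 16 without 35S:CO ZT4 replicate 2, and the interaction with tissue gave 550 and 333 without a filter.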

Other observations

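No test in this part was planned, and the values were chosen after they were seen. The locus AT3G28820 stood at 0 FPKM in seedlings, in Col-0 and co-10 petals at ZT4 and near 0 in Col-0 petals at ZT16 (0.185 FPKM), and at 21.0 and 33.2 FPKM in 35S:CO petals at ZT4 and ZT16 and 67.6 FPKM in co-10 petals at ZT16. MIR2936 stood at 159 and 137 FPKM in Col-0 and 35S:CO seedlings, 5.94 FPKM in co-10 petals at ZT4 and 275 FPKM at ZT16. VSP1, a vegetative storage protein gene, stood at 31.1 and 264 FPKM in Col-0 and 35S:CO seedlings and at 398 and 316 FPKM in the corresponding petals at ZT16, and VSP2 at 65.2 and 373 FPKM and at 464 and 266 FPKM. The share of summed FPKM in ribosomal RNA loci was highest in 35S:CO petals of ZT4 replicate 2, at 48.8%, and lowest among petals in co-10 ZT16 replicate 2, at 3.82%.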
